A study of Mus musculus with 33 samples.

How the data were processed

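RNA levels were measured in 15 libraries of P19 cells, 3 for each of 5 groups (D0, D3DMSO, D3RA, D6DMSO and D6RA), grouped by the treatment and day in the sample titles. The series holds 33 samples, and the 18 chromatin immunoprecipitation samples were left out because the processed table holds RNA values only. Libraries were made from total RNA with a stranded kit that depletes ribosomal RNA and sequenced single end on a NextSeq500, per the labels. Tools listed are Bowtie2 2.2.9, SAMtools 0.1.19, FastQC 0.11.2, Trimmomatic 0.32, STAR 2.6.0c, featureCounts, edgeR and limma with the mm9 genome, per the submitters' processing notes, which do not say which of them made this table.

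The deposited table holds log2 values for 14717 Ensembl gene IDs, of which 14228 were matched to a symbol and 489 were not. Its lowest value is 1.0. After undoing the log2, taking off a constant per library and a count of 0.5, 100% of the values lay within 0.05 of a whole number, so these whole numbers were taken as recovered counts. Levels in the text are recovered counts in CPM, as the mean and SD of 3 libraries. The ratios of the library sizes used for CPM follow the deposited scale. Their geometric mean was set to that of the non-mitochondrial counts. These sizes were 22.8 to 23.8 M in D6DMSO and 24.4 to 31.9 M in D6RA, which is less than the total counts. Total counts per library are given at the start of the report. Where a group holds 0 counts of a gene, a fold is given as at least the value for 3 counts over the group. Where it holds 1 to 3 counts, the ratio of the counts, summed over the libraries of each group, is given with its 95% counting interval. That interval holds counting error only and leaves out the spread between libraries.

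Genes were compared with limma 3.58.1 in R 4.3.3, with a trend in the variance, on the deposited log2 values of all 14717 genes (the filter of the design removed none). The fit had 1 coefficient for each of the 5 groups and 10 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and those with a log2 fold change of at least 1 in either direction were also counted. The comparisons were D3DMSO with D0, D3RA with D0, D3RA with D3DMSO, D6RA with D6DMSO, D6RA with D3RA, D6DMSO with D3DMSO and the interaction, which is the RA minus DMSO difference at D6 less that at D3. The overlap of the comparisons with D0 was set beside 100 simulations of unchanged groups against the same D0 libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

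The 21 gene lists were written from general knowledge before the data were examined: pluripotency, retinoic acid response, anterior Hox, posterior Hox, neural progenitor, neuronal differentiation, primitive streak and nascent mesoderm, cardiac mesoderm, cardiac sarcomere, visceral and definitive endoderm, parietal endoderm, endothelial and blood, smooth muscle and mesenchyme, skeletal muscle, neural crest and glia, epithelium, nuclear lamina and envelope, H3K9 methylation, proliferation, hypoxia and glycolysis, and immediate early and stress. Some genes are on several lists. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 21 lists of a comparison, and again with the correlation estimated from the data.

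Genes were named by a rule with 3 parts. The first is a fixed panel with Pou5f1, Nanog, Sox2, Cyp26a1, Pax6, Tubb3, T, Mixl1, Gata4, Gata6, Nkx2-5, Lmna and Lmnb1. The second is, per comparison, the 3 called genes with the highest and the 3 with the lowest log2 fold change among those with at least 10 CPM in the higher group and no overlap between libraries, leaving out predicted and unnamed genes, mitochondrial genes and small RNAs. The third is, per comparison and list that passed its test, and always for 10 of the lists between treatments, the 2 called members with the highest and the 2 with the lowest log2 fold change at 1 CPM or more in the higher group. Whole lists were dropped from the text, highest list p first, to stay near 30 genes per comparison. Besides these lists and the panel genes Mixl1 and Nkx2-5, which were not analysed here, 1 gene of the panel and 1 of the third part are not reported here.

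Alternatives fixed in advance were quantile normalization, no filter, a stricter filter of 5 CPM in 3 libraries (12552 genes), limma without the trend, a fit of the compared groups alone, a replicate block and leaving out each library in turn. Those chosen after seeing the data were voom weights, median-of-ratios scaling, a count added in proportion to library size (2 on average), thinning of all libraries to the smallest scaled size of 2189364 counts, a filter of 1 CPM in 1 group (14716 genes) and a fit of the D0 and D3 libraries alone.

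The scripts were tested on simulated counts with 200 genes of at least 1 CPM changed by known folds, 50 per fold, among 14717. For D3RA with D3DMSO, 58, 78, 90 and 96% of genes changed by 1.5, 2, 4 and 8-fold were called, along with 16 of 14517 unchanged genes (0.11%). For D6RA with D6DMSO the shares were 52, 62, 98 and 96%, with 2 of 14517 unchanged genes (0.01%). In the simulated list test 1 of 1 changed list and 0 of 20 unchanged lists were called.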

Results

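P19 cells, a mouse embryonal carcinoma line that resembles early embryonic cells and can be turned into several lineages, were profiled by sequencing of total RNA depleted of ribosomal RNA. The 15 libraries fall into 5 groups of 3. D0 is undifferentiated cells. D3RA and D6RA are cells 3 and 6 days into differentiation with all-trans retinoic acid (1 µM), the standard route of this line to neurons, and D3DMSO and D6DMSO are cells at the same days of differentiation with dimethyl sulfoxide, its route to mesoderm and cardiac muscle. The series also holds 18 chromatin immunoprecipitation samples for H3K9me2 and H3, which are not analysed here. Its design text calls the 3 samples of a group biological replicates but does not say whether they came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

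Total counts per library were 7.13 to 9.88 M in D0, 5.86 to 6.87 M in D3DMSO, 3.55 to 9.82 M in D3RA, 39.0 to 44.5 M in D6DMSO and 38.2 to 49.6 M in D6RA. The table holds 11 genes of the mitochondrial genome. All 11 had 0 counts in each of the 9 libraries of D0 and D3. They took 49.8 to 55.8% of the counts in D6DMSO and 41.6 to 42.6% in D6RA. Most of these counts were of the mitochondrial ribosomal RNA genes mt-Rnr2 (31.6 to 42.5% of all counts in the D6 libraries) and mt-Rnr1 (6.55 to 11.1%). Lars2, Gm15564, ENSMUSG00000045999 and ENSMUSG00000093077, chosen after their values were seen, took 8.86 to 23.2% of the non-mitochondrial counts in D0, 3.09 to 32.8% in D3DMSO, 1.97 to 45.7% in D3RA and at most 1.70% in D6. Spearman correlations of libraries were 0.984 to 0.999 within groups and 0.775 to 0.943 between groups, across genes, which are not independent replicates.

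**Figure D1:**
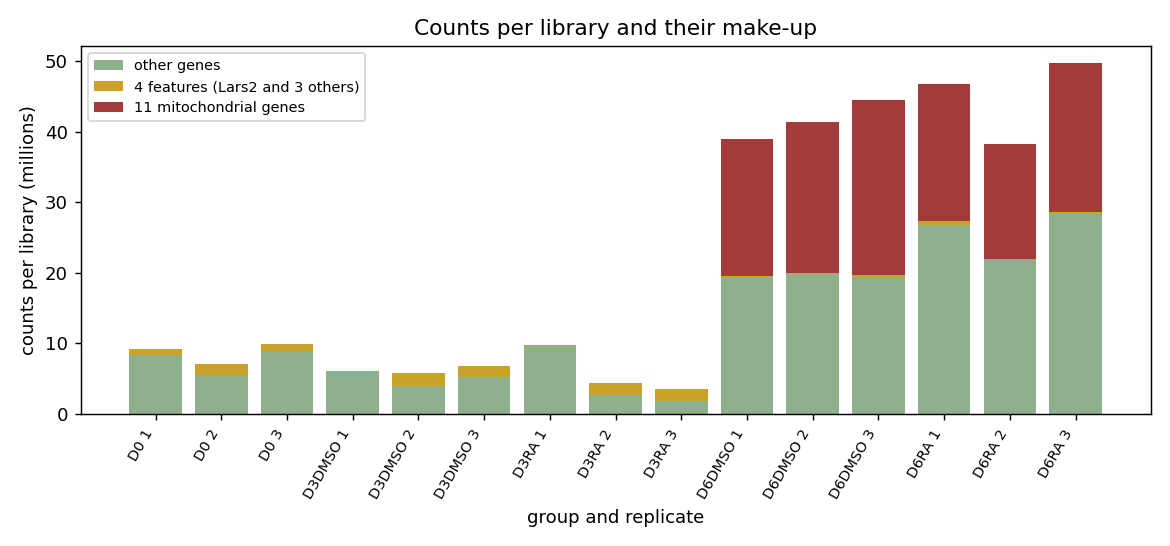
Counts per library in M (y axis) for the 15 libraries (x axis, group and replicate), stacked as the 11 mitochondrial genes, the 4 features named with Lars2 and all other genes. The 6 D6 libraries hold 38.2 to 49.6 M counts, of which 41.6 to 55.8% are mitochondrial, and the 9 others hold 3.55 to 9.88 M and none.

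Levels are the mean ± SD of the 3 libraries of a group in CPM. Counts were scaled to the library size defined above, not to the total counts. Differences are log2 fold changes ± SE from limma with Benjamini-Hochberg adjustment over all genes of the table. Gene lists fixed in advance were tested with camera, adjusted over the 21 lists of a comparison. Each list is given with its members called higher and lower. The counts adjusted over the list alone were the same in 126 of 147 pairs of list and comparison and differed by at most 2 genes in the others, which are given where such a list is described. Gene counts in the text refer to an adjusted p below 0.05. In each of the 7 comparisons, which direction holds more called genes turned under 1 or more alternatives.

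Of the panel genes, Pou5f1 and Nanog, transcription factors of pluripotent cells, were at 1320 ± 98 and 76.7 ± 6.8 CPM in D0. Pou5f1 was at 555 ± 250 CPM in D3DMSO, 47 ± 6 CPM in D6DMSO, 1.79 ± 2 CPM in D3RA and 0.115 ± 0.12 CPM in D6RA. Nanog was at 68.1 ± 24, 12 ± 0.94, 0.0911 ± 0.16 and 0.0598 ± 0.026 CPM in the same order. Sox2, shared by pluripotent and neural cells, was at 228 ± 24 CPM in D0, 67.4 ± 11 in D3DMSO, 49.8 ± 16 in D6DMSO, 147 ± 12 in D3RA and 187 ± 11 in D6RA. Lmna, which encodes the A-type lamins of the nuclear lamina, was at 12.1 ± 3.2 CPM in D0, 9.17 ± 2.5 in D3DMSO, 18.4 ± 0.36 in D6DMSO, 5.23 ± 1 in D3RA and 6.4 ± 0.65 in D6RA. Lmnb1, which encodes lamin B1, was at 255 ± 5.2, 179 ± 4.7, 199 ± 8.5, 184 ± 30 and 255 ± 10 CPM in that order. Mixl1 and Nkx2-5, which were also on the panel, were not analysed here.

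**Figure D2:**
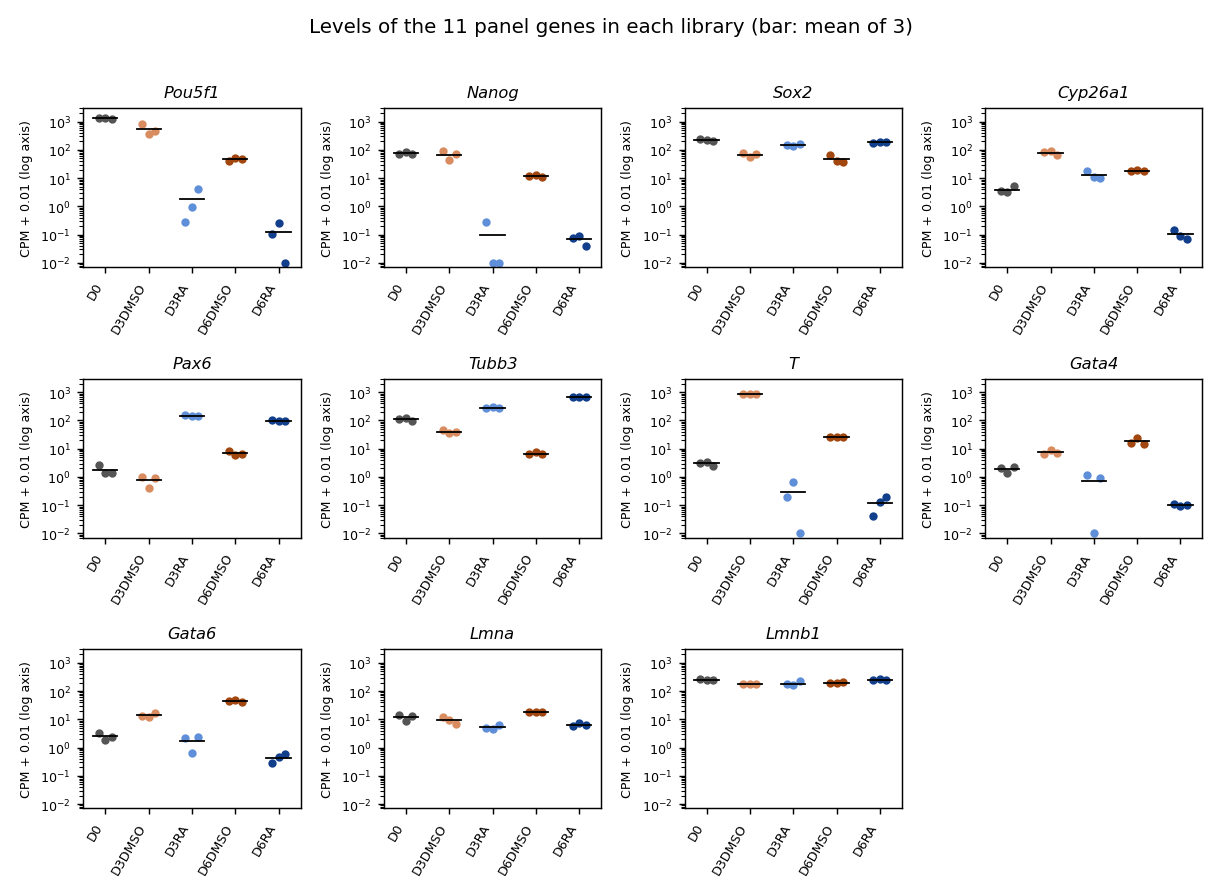
Levels of the 11 panel genes in each library (y axis, CPM + 0.01 on a log axis, so that 0 plots at 0.01; x axis, group; points, the 3 libraries; bar, their mean). T reached 874 CPM in D3DMSO and 0.278 CPM in D3RA, Pax6 reached 149 CPM in D3RA, and Pou5f1 fell from 1320 CPM in D0 to 1.79 CPM in D3RA.

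In the comparison of D3DMSO with D0, which asks what the DMSO route changed in the first days, genes of the primitive streak and nascent mesoderm rose together. All 17 measured members of that list were called higher (list adjusted p = 1.6e-13 and 0.00785 with an estimated correlation). T (brachyury), the transcription factor that marks nascent mesoderm, rose from 3 ± 0.51 to 874 ± 19 CPM (n = 3 per group; log2 fold change 8.17 ± 0.46, adjusted p = 3.43e-10). Cdx2, a caudal homeobox factor, rose from 2 counts in the 3 D0 libraries to 95.6 ± 20 CPM, a ratio of 1240 with a 95% counting interval of 343 to 10300. Wnt3a, a Wnt ligand of the streak, had 0 counts in D0 and 42.7 ± 12 CPM in D3DMSO, at least 380-fold higher with the floor at 3 counts over the group.

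Hox genes rose along with them in D3DMSO. All 14 anterior members (paralogs 1 to 5) were called higher (list adjusted p = 4.6e-11, and adjusted p = 0.108 with an estimated correlation). All 10 posterior members (paralogs 6 to 13) were also called higher (list adjusted p = 1.1e-05, and adjusted p = 0.204 with an estimated correlation). Hoxb1 and Hoxa2 had 0 counts in D0 and were at 36.4 ± 15 and 16.5 ± 7.4 CPM, at least 323-fold and 147-fold higher. Hoxd9 rose from 0.137 ± 0.24 to 13.5 ± 8 CPM, and Hoxb9 from 2 counts to 4.01 ± 2.8 CPM, a ratio of 48.9 (13 to 412). Foxb1, a forkhead factor, had 0 counts in D0 and 40.2 ± 5.7 CPM in D3DMSO, at least 358-fold higher. Cyp26a1, which breaks down retinoic acid, rose by 4.35 ± 0.25 on the log2 scale to 81.3 ± 13 CPM, and the retinoic acid response list had 8 members higher and 5 lower of 16 (list adjusted p = 0.0269, and adjusted p = 0.108 with an estimated correlation).

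Of the 16 measured genes of cardiac mesoderm, 10 were higher and 1 lower in D3DMSO (list adjusted p = 0.000777, and adjusted p = 0.108 with an estimated correlation). Kdr, a VEGF receptor of early mesoderm, rose from 0.904 ± 0.48 to 46.8 ± 15 CPM, and Foxc1 from 0.628 ± 0.28 to 30 ± 6 CPM. Gata4 and Gata6, factors of cardiac mesoderm and endoderm, rose to 7.47 ± 1.2 and 14 ± 2.2 CPM from 1.91 ± 0.43 and 2.55 ± 0.77 CPM. The Gata4 call (adjusted p = 0.00597) was lost on thinning all libraries to the smallest (0.0528, within a range of 0.000126 to 0.0528 over 17 alternatives). Myocd, a coactivator of cardiac and smooth muscle genes, was called lower (0.694 ± 0.079 against 1.63 ± 0.37 CPM, adjusted p = 0.0165). Its call was lost without D0 replicate 2 (adjusted p = 0.0689), and over 17 alternatives its adjusted p ran from 0.00205 to 0.143.

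The pluripotency list had 17 of 27 members lower in D3DMSO, 3 higher and 7 not called (list adjusted p = 0.00224, and adjusted p = 0.108 with an estimated correlation). Nr0b1 fell from 64.6 ± 1.5 to 1.89 ± 1.2 CPM (log2 -5.27 ± 0.44, adjusted p = 4.47e-08) and Utf1 from 99 ± 3.2 to 9.38 ± 4.1 CPM. Lefty2, a Nodal antagonist, rose from 3.54 ± 0.71 to 59.8 ± 18 CPM. Fgf4 was at 12 ± 2.5 CPM in D0 and 41.6 ± 7.5 CPM in D3DMSO (adjusted p = 0.0259). That call was lost without D0 replicate 2, D0 replicate 3, D3DMSO replicate 2 or D3DMSO replicate 3 (adjusted p = 0.0663, 0.0726, 0.075 and 0.0628, within a range of 2.5e-07 to 0.075 over 17 alternatives). Sox2 fell by 1.76 on the log2 scale (± 0.16, adjusted p = 1.48e-07). Pou5f1 and Nanog were not called (adjusted p = 0.184 and 0.547). The spread used for Pou5f1 is shared with the D3RA and D6RA libraries, where it was near 0, and in a fit of the 6 libraries alone its adjusted p was 0.000822, within a range of 1.37e-05 to 0.365 over 17 alternatives.

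Cell cycle genes were lower in D3DMSO for 18 of 25 members and higher for 1 (proliferation list, adjusted p = 9.18e-05, and adjusted p = 0.19 with an estimated correlation). Ccnd1 fell from 77.2 ± 6.1 to 18.1 ± 3.7 CPM and Ccne1 from 143 ± 14 to 47.8 ± 0.63 CPM. Ccne2 rose from 37.4 ± 2.2 to 72.1 ± 9.4 CPM. Of 17 genes of hypoxia and glycolysis, 12 were lower and 2 higher (list adjusted p = 0.00224, and adjusted p = 0.303 with an estimated correlation). Bnip3 fell from 193 ± 42 to 49.7 ± 10 CPM and Adm from 9.05 ± 2.7 to 1.74 ± 0.56 CPM, and Vegfa rose from 31.3 ± 4.6 to 63.5 ± 12 CPM. Car9 was at 0.444 ± 0.23 and 1.08 ± 0.49 CPM (adjusted p = 0.0278). Its call was lost without D0 replicate 3 or D3DMSO replicate 2 (adjusted p = 0.149 and 0.129, within a range of 0.0135 to 0.149 over 17 alternatives). Tubb3, a tubulin of neurons, fell from 112 ± 12 to 40.1 ± 4.4 CPM, and Lmnb1 by 0.51 on the log2 scale (± 0.09, adjusted p = 9.66e-05), while Lmna was not called (adjusted p = 0.131, within a range of 0.0209 to 0.494 over 17 alternatives). Ntrk2, the BDNF receptor, and Calcr, the calcitonin receptor, fell by 4.62 and 5.1 on the log2 scale (± 0.79 and ± 0.68). Pax6 was at 1.8 ± 0.66 and 0.769 ± 0.31 CPM (log2 -1.14 ± 0.24, adjusted p = 0.000795), and its call was lost and its direction turned when all libraries were thinned to the smallest (log2 0.65, adjusted p = 0.178, within a range of 8.61e-05 to 0.178 over 17 alternatives).

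In all, limma with Benjamini-Hochberg adjustment called 8253 genes between D3DMSO and D0, 4155 higher and 4098 lower in D3DMSO, of which 1494 and 1167 differed by at least 2-fold.

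With retinoic acid, the comparison of D3RA with D0 showed Pou5f1 and Nanog near the detection limit and Pax6 raised. Pou5f1 fell from 1320 ± 98 to 1.79 ± 2 CPM (n = 3 per group; log2 -10.14 ± 0.83, adjusted p = 1.34e-08). Nanog had 3 counts in the 3 D3RA libraries, 409-fold lower than D0 with a 95% counting interval of 140 to 1990. Pax6, a factor of the neural tube, rose from 1.8 ± 0.66 to 149 ± 8.2 CPM (log2 6.38 ± 0.24, adjusted p = 1.32e-12). Of the 27 pluripotency genes, 24 were lower and 1 higher (list adjusted p = 3.48e-10 and 0.00381 with an estimated correlation).

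L1td1, an RNA-binding protein of pluripotent cells, fell from 356 ± 42 to 0.826 ± 0.93 CPM, and Trh, the precursor of thyrotropin-releasing hormone, from 1580 ± 120 to 3.2 ± 3.2 CPM in D3RA. Sox2 fell by 0.63 on the log2 scale (± 0.16). Esrrb, an orphan nuclear receptor, was the member called higher (5.24 ± 2.2 against 1.54 ± 0.46 CPM, adjusted p = 0.017). Its call was lost without D0 replicate 3, D3RA replicate 1 or D3RA replicate 2 (adjusted p = 0.0606, 0.0681 and 0.0522, within a range of 0.000457 to 0.0681 over 16 alternatives).

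All 14 anterior and all 10 posterior Hox genes were called higher in D3RA than in D0 (list adjusted p = 1.63e-10 and 2.16e-06, and adjusted p = 0.0806 and 0.16 with an estimated correlation). Hoxa5, Hoxb6 and Hoxb7 had 0 counts in D0 and were at 196 ± 14, 184 ± 12 and 46.8 ± 2.6 CPM, at least 1740-fold, 1640-fold and 417-fold higher. Hoxb4 rose from 1 count to 176 ± 7.9 CPM, a ratio of 4740 (851 to 187000). The retinoic acid response list had 14 of 16 members higher and 2 lower (list adjusted p = 1.15e-05 and 0.00381 with an estimated correlation). Cyp26b1, a retinoic acid hydroxylase, rose from 0.265 ± 0.14 to 168 ± 32 CPM, and Cyp26a1 from 3.97 ± 0.99 to 13.2 ± 4.4 CPM. Rarg, a retinoic acid receptor, fell from 23.5 ± 1.2 to 3.33 ± 1.3 CPM and Rdh10, which makes retinal, from 16.6 ± 1.8 to 7.65 ± 0.44 CPM.

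Neural progenitor genes were higher in D3RA for 25 of 28 members and lower for 3 (list adjusted p = 3.39e-09 and 0.00231 with an estimated correlation), and neuronal genes were higher for 33 of 39 and lower for 2 (6.24e-10 and 0.00381). Pax7, of the dorsal neural tube, had 0 counts in D0 and 29.1 ± 6.4 CPM in D3RA, at least 258-fold higher, and Pou3f3 rose from 0.168 ± 0.21 to 81.2 ± 4.1 CPM. Nhlh2, a basic helix-loop-helix factor of new neurons, and Chrna3, a nicotinic receptor subunit, had 0 counts in D0 and were at 77.6 ± 12 and 32.5 ± 7.5 CPM, at least 690-fold and 289-fold higher. Tubb3 rose from 112 ± 12 to 286 ± 21 CPM. Zic2 fell from 52.3 ± 2.4 to 10.2 ± 1.1 CPM, and Stmn2 from 171 ± 7.7 to 76.2 ± 11 CPM. Phox2a and Nkx6-1 each had 1 count in the D3RA libraries, 74.2-fold (13.1 to 2960) and 49.9-fold (8.71 to 1990) lower than in D0.

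Endothelial and blood genes were also raised in D3RA, with 13 of 15 members higher and 1 lower than in D0 (list adjusted p = 3.12e-05 and 0.00381 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, rose from 3 counts to 35.4 ± 6.3 CPM, a ratio of 303 (103 to 1480). Emcn, an endothelial sialomucin, rose from 1 count to 19.3 ± 4.2 CPM, a ratio of 504 (89.9 to 20000). Etv2, a factor that starts the endothelial program, fell from 3.1 ± 0.52 to 0.534 ± 0.26 CPM (adjusted p = 7.28e-05, lost on thinning all libraries to the smallest at 0.175, within a range of 2.79e-06 to 0.175 over 17 alternatives). All 11 epithelial genes were lower (list adjusted p = 1.15e-05, and adjusted p = 0.0806 with an estimated correlation). Cdh1, which encodes E-cadherin, fell from 81.2 ± 12 to 0.947 ± 0.38 CPM, and Esrp1, an epithelial splicing factor, from 12.2 ± 0.72 to 0.274 ± 0.24 CPM. Of 17 genes of hypoxia and glycolysis 15 were lower and 0 higher (list adjusted p = 1.67e-06, and adjusted p = 0.124 with an estimated correlation). Slc2a3, a glucose transporter, fell from 1480 ± 130 to 71.8 ± 9.5 CPM and Adm from 9.05 ± 2.7 to 0.152 ± 0.26 CPM.

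T fell from 3 ± 0.51 to 0.278 ± 0.34 CPM in D3RA, and Gata4 was at 0.699 ± 0.62 CPM (adjusted p = 0.012, lost in the fit of the 6 libraries alone at 0.0515 and under voom weights at 0.0789, within a range of 0.00107 to 0.0789 over 17 alternatives). Gata6 was not called (1.68 ± 0.89 CPM, adjusted p = 0.13, within a range of 0.0346 to 0.71 over 17 alternatives). Lmna fell by 1.16 and Lmnb1 by 0.48 on the log2 scale (± 0.22 and ± 0.09, adjusted p = 0.000154 and 9.85e-05). The proliferation list had 17 members lower and 3 higher of 25 (adjusted p = 0.00217), the cardiac sarcomere list 10 lower and 0 higher of 14 (0.0177) and the immediate early and stress list 11 lower and 1 higher of 17 (0.0367), with adjusted p = 0.256, 0.203 and 0.478 with an estimated correlation. The last list lost its call without D0 replicate 3 (0.0513) or D3RA replicate 2 (0.0824). By limma with Benjamini-Hochberg adjustment, 10147 genes were called between D3RA and D0, 5151 higher and 4996 lower, of which 2378 and 2103 differed by at least 2-fold.

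The treatments shared part of their change from D0. At D3, 2614 genes were called higher in both and 2540 lower in both, against 1454 and 1391 for independent lists of those sizes, and 1176 genes were called in opposite directions, against 2845. Across genes, which are not independent replicates, the log2 fold changes had a covariance of 0.656, against 0.032 from 100 simulations of unchanged groups set against the same D0 libraries, a difference of 0.624. The correlation of the log2 fold changes was 0.42, and 0.5 in the simulations, where at most 1 gene was called in the same direction. The 3 D0 libraries cannot be split into 2 sets of at least 2, so part of the excess over independent lists may come from the shared controls. Hox genes, Kdr and Cyp26a1 were among those higher with either treatment.

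**Figure D3:**
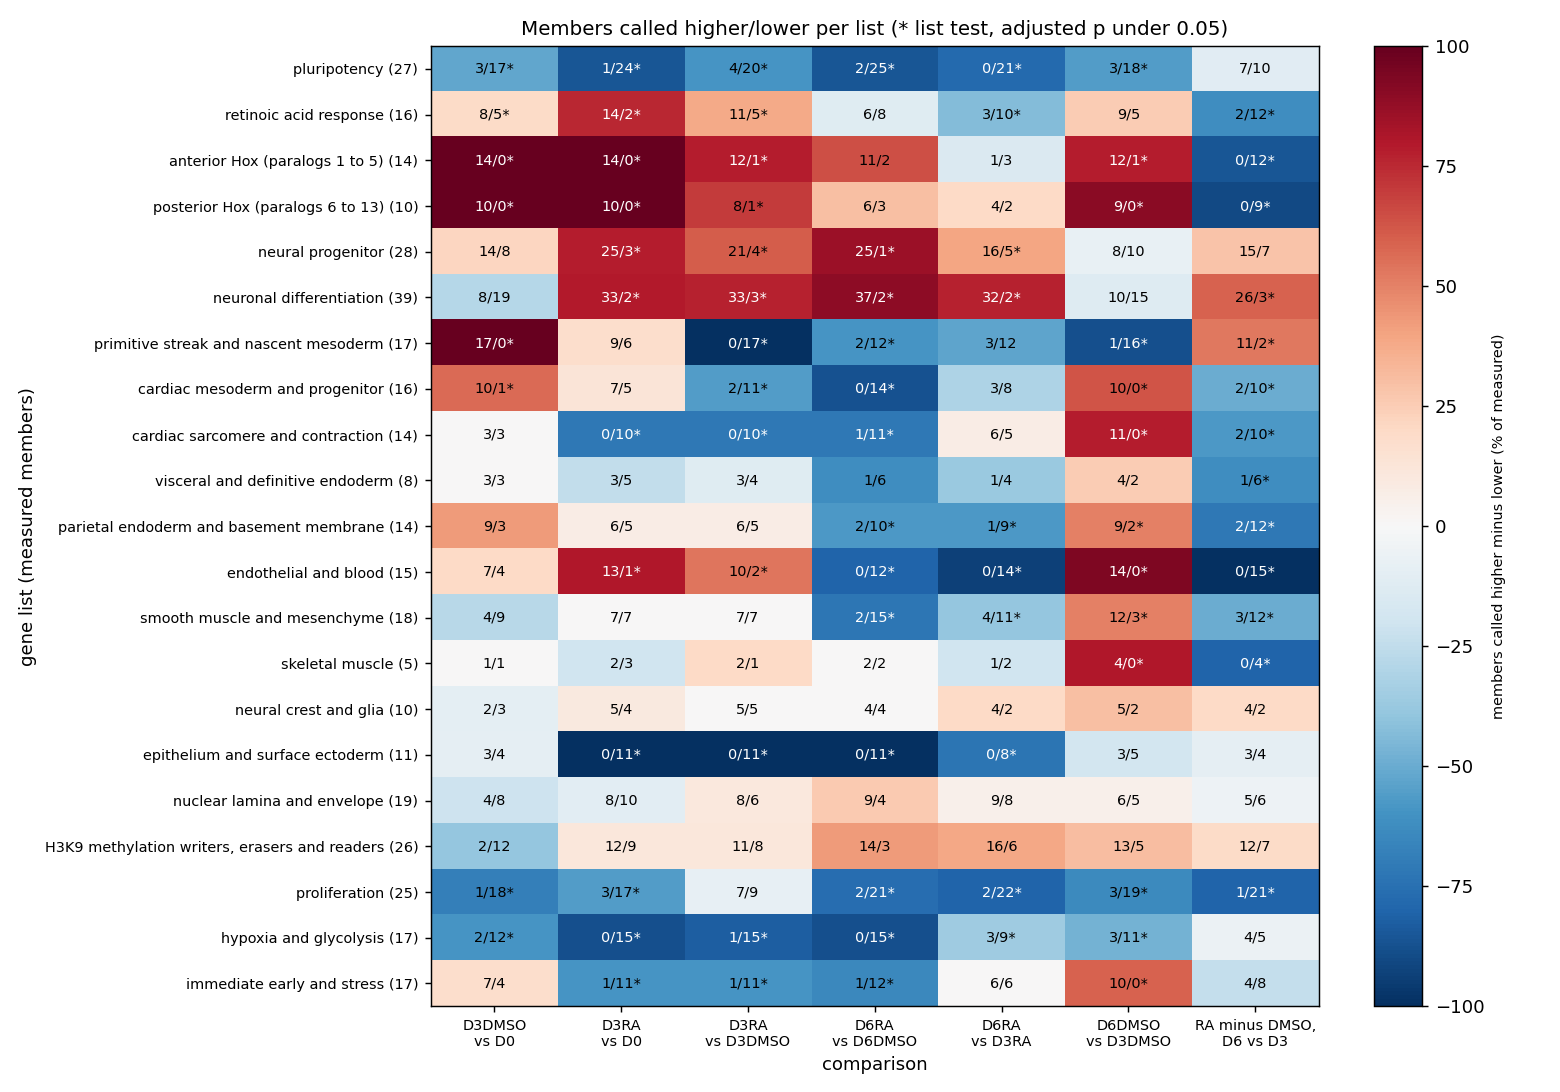
Members of the 21 gene lists (y axis, with the number measured) called higher and lower in each comparison (x axis), written in the cells. Color shows members called higher minus lower as a percentage of those measured, and a star marks a list test with an adjusted p under 0.05. The primitive streak list had 17 of 17 members higher in D3DMSO than in D0 and 17 of 17 lower in D3RA than in D3DMSO.

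The direct comparison of D3RA with D3DMSO asks how the neural and mesodermal routes differed at day 3. T was at 0.278 ± 0.34 CPM in D3RA and 874 ± 19 CPM in D3DMSO (n = 3 per group; log2 -11.29 ± 0.46, adjusted p = 3.14e-12). Wnt8a, a Wnt ligand of the primitive streak, had 0 counts in D3RA and 165 ± 30 CPM in D3DMSO, at least 895-fold lower in D3RA. In the other direction, Pax6 was at 149 ± 8.2 CPM in D3RA and 0.769 ± 0.31 CPM in D3DMSO (log2 7.52 ± 0.24, adjusted p = 2.33e-13). Nhlh2 had 0 counts in D3DMSO and 77.6 ± 12 CPM in D3RA, at least 480-fold higher.

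All 17 streak genes were lower in D3RA than in D3DMSO (list adjusted p = 1.5e-10 and 0.00729 with an estimated correlation), among them Cdx2 with 1 count against 95.6 ± 20 CPM, a ratio of 1510 (271 to 59700). Neuronal genes were higher in D3RA for 33 of 39 members and lower for 3, or 33 and 4 adjusted over the list alone (list adjusted p = 1.35e-12 and 0.00474 with an estimated correlation). Dcx, the microtubule protein of migrating neurons, was at 107 ± 21 CPM in D3RA and 0.465 ± 0.29 in D3DMSO, and Tubb3 at 286 ± 21 and 40.1 ± 4.4 CPM. Lhx1, a factor of both axial mesoderm and neurons, was lower in D3RA (25.1 ± 5.5 against 74 ± 19 CPM), as was Phox2a, with 1 count, 33.2-fold lower (5.61 to 1350). Neural progenitor genes were higher for 21 of 28 members and lower for 4 (1.33e-06 and 0.00474). Sox21 and Dbx1 had 0 counts in D3DMSO and were at 42 ± 4.4 and 37.6 ± 7.1 CPM in D3RA, at least 260-fold and 233-fold higher. Dll3, a Notch ligand of the presomitic mesoderm and of neurons, was lower in D3RA (10.3 ± 2.2 against 82.5 ± 12 CPM), and Nkx6-1 had 1 count there, 19.2-fold lower (3.11 to 794). Nr2f1, a nuclear receptor of the hindbrain and forebrain, had 1 count in D3DMSO and 105 ± 8.4 CPM in D3RA, a ratio of 1870 (335 to 73800).

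Pluripotency genes were lower in D3RA than in D3DMSO for 20 of 27 members and higher for 4 (list adjusted p = 6.61e-07 and 0.0105 with an estimated correlation). Pou5f1 was at 1.79 ± 2 against 555 ± 250 CPM (log2 -8.81 ± 0.83, adjusted p = 1.04e-07), Nanog had 3 counts, 385-fold lower (132 to 1870), and Fgf4 had 0 counts, at least 225-fold lower. Esrrb (5.24 ± 2.2 against 0.391 ± 0.34 CPM), Klf2 (6.67 ± 0.73 against 3.04 ± 1.1 CPM) and Sox2 (log2 1.13 ± 0.16) were higher in D3RA. The call of Klf2 (adjusted p = 0.0011) was lost when all libraries were thinned to the smallest (0.0828, within a range of 0.000217 to 0.0828 over 17 alternatives).

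Genes of the retinoic acid response were higher in D3RA for 11 of 16 members and lower for 5 (list adjusted p = 0.019, and adjusted p = 0.0668 with an estimated correlation). Cyp26b1 had 1 count in D3DMSO and 168 ± 32 CPM in D3RA, a ratio of 2910 (522 to 115000). Rarb, a receptor gene that retinoic acid induces, was at 263 ± 17 CPM in D3RA and 1.59 ± 0.23 CPM in D3DMSO (log2 7.31 ± 0.14, adjusted p = 1.21e-15). Aldh1a2, which makes retinoic acid in mesoderm, was at 0.764 ± 0.38 CPM in D3RA and 214 ± 29 CPM in D3DMSO (log2 -7.91 ± 0.26, adjusted p = 3.47e-13), and Cyp26a1 was also lower in D3RA (13.2 ± 4.4 against 81.3 ± 13 CPM). Anterior Hox genes were higher in D3RA for 12 of 14 members and lower for 1, and posterior Hox genes higher for 8 of 10 and lower for 1 (list adjusted p = 2.12e-05 and 0.00126, and adjusted p = 0.228 and 0.303 with an estimated correlation). Hoxb6 (184 ± 12 against 0.549 ± 0.52 CPM), Hoxb8 (21.9 ± 4.4 against 0.657 ± 0.51), Hoxb5 (71.8 ± 20 against 0.491 ± 0.47) and Hoxc5 (75.4 ± 4.7 against 0.508 ± 0.63) were higher in D3RA. Hoxb1 (5.03 ± 0.8 against 36.4 ± 15 CPM) and Hoxd9 (0.891 ± 0.42 against 13.5 ± 8 CPM) were lower.

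Of 15 endothelial and blood genes, 10 were higher and 2 lower in D3RA than in D3DMSO (list adjusted p = 0.000548 and 0.0113 with an estimated correlation). Emcn had 0 counts in D3DMSO and 19.3 ± 4.2 CPM in D3RA, at least 120-fold higher, and Tie1, a receptor of endothelial cells, 2 counts and 33.3 ± 10 CPM, a ratio of 344 (94.7 to 2840). Flt1 (11 ± 0.45 against 23.7 ± 1.8 CPM) and Etv2 (0.534 ± 0.26 against 6.38 ± 1.8 CPM) were lower. Cardiac mesoderm genes were lower in D3RA for 11 of 16 members and higher for 2 (list adjusted p = 0.0182, and adjusted p = 0.154 with an estimated correlation). Pdgfra, a receptor of mesoderm, was at 3.14 ± 0.42 against 115 ± 34 CPM, Wnt11 at 0.291 ± 0.27 against 7.51 ± 1.4 CPM, Gata4 at 0.699 ± 0.62 against 7.47 ± 1.2 CPM and Gata6 at 1.68 ± 0.89 against 14 ± 2.2 CPM. Mef2c was higher (16.7 ± 3.5 against 2.51 ± 0.38 CPM). Smarcd3 was at 5.55 ± 1.2 in D3RA and 3.46 ± 1.9 CPM in D3DMSO (adjusted p = 0.0481). Its call was lost without D3DMSO replicate 3, D3RA replicate 1 or D3RA replicate 3 (adjusted p = 0.339, 0.109 and 0.131, within a range of 0.00717 to 0.446 over 17 alternatives). Sarcomere genes were lower for 10 of 14 members and higher for 0 (list adjusted p = 0.00897, and adjusted p = 0.154 with an estimated correlation). In D3DMSO against D0 that list did not pass, with 3 higher and 3 lower, or 1 and 3 adjusted over the list alone (list adjusted p = 0.921). Myl4, an atrial myosin light chain, had 1 count in D3RA, 72.6-fold lower (12.7 to 2900), and Tnni1, a troponin of embryonic heart, 3 counts, 19.8-fold lower (6.5 to 98.5).

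All 11 epithelial genes were lower in D3RA than in D3DMSO (list adjusted p = 2.12e-06, and adjusted p = 0.0618 with an estimated correlation). Cdh1 was at 0.947 ± 0.38 against 117 ± 29 CPM and Grhl3 at 0.243 ± 0.23 against 9.95 ± 3.5 CPM. Hypoxia and glycolysis genes were lower for 15 of 17 members and higher for 1 (list adjusted p = 1.8e-05, and adjusted p = 0.154 with an estimated correlation). Slc2a3 was at 71.8 ± 9.5 against 918 ± 54 CPM and Ndrg1 at 2.45 ± 1.5 against 36.5 ± 2.7 CPM. Slc2a1, the other glucose transporter, was higher (525 ± 30 against 239 ± 36 CPM). Immediate early and stress genes were lower for 11 of 17 members and higher for 1 (list adjusted p = 0.00897, and adjusted p = 0.303 with an estimated correlation). Chac1 (6.13 ± 1.8 against 90.5 ± 19 CPM) and Trib3 (4.2 ± 0.74 against 57.5 ± 17 CPM), targets of the ATF4 stress pathway, were lower in D3RA, and Jun was higher (99.1 ± 11 against 36.2 ± 14 CPM).

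The lists on the subject of the series did not pass the list test between the treatments at day 3. Of 19 nuclear lamina and envelope genes, 8 were higher and 6 lower in D3RA (list adjusted p = 0.403). Syne2, which encodes a nesprin, was higher in D3RA (483 ± 44 against 175 ± 30 CPM), as was the pore protein gene Nup210 (118 ± 5.4 against 59.4 ± 11 CPM). Lemd3 (33.7 ± 5.8 against 46.2 ± 3.6 CPM) and Lmna (log2 -0.77 ± 0.22, adjusted p = 0.00575) were lower. The Lmna call was lost when all libraries were thinned to the smallest (adjusted p = 0.0504, within a range of 0.00112 to 0.0504 over 17 alternatives). Lmnb1 was not called (log2 0.02 ± 0.09, adjusted p = 0.822). Of 26 writers, erasers and readers of H3K9 methylation, 11 were higher and 8 lower in D3RA (list adjusted p = 0.51). Against D0, 2 were higher and 12 lower in D3DMSO (list adjusted p = 0.051, and adjusted p = 0.19 with an estimated correlation). Without each library in turn that list adjusted p ran from 0.0183 to 0.141. In D3RA against D0, 12 were higher and 9 lower (list adjusted p = 0.958). Prdm16 had 2 counts in D3DMSO and 13.5 ± 3 CPM in D3RA, a ratio of 113 (30.8 to 937), and Mecom, its close relative, was also higher (71.4 ± 6.3 against 2.06 ± 0.9 CPM). Cdyl (25 ± 1.1 against 39.1 ± 4.2 CPM) and the demethylase gene Kdm4c (52.6 ± 4.8 against 82.4 ± 7.9 CPM) were lower. Between D3RA and D3DMSO, limma with Benjamini-Hochberg adjustment called 9136 genes, 4517 higher and 4619 lower in D3RA, of which 1745 and 1894 differed by at least 2-fold.

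At day 6, D6RA was compared with D6DMSO. Tubb3 was at 677 ± 1.4 CPM in D6RA and 6.67 ± 0.63 CPM in D6DMSO (n = 3 per group; log2 6.67 ± 0.09, adjusted p = 9.55e-18), and Dcx at 831 ± 48 and 0.603 ± 0.26 CPM (log2 10.48 ± 0.34, adjusted p = 9.4e-14). Actc1, the cardiac actin, was at 62.6 ± 6.3 CPM in D6DMSO and had 3 counts in D6RA, 1810-fold lower (618 to 8770). Neuronal genes were higher in D6RA for 37 of 39 members and lower for 2 (list adjusted p = 1.04e-18 and 0.000859 with an estimated correlation). Sarcomere genes were lower for 11 of 14 members and higher for 1 (4.83e-05 and 0.0438).

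Among neuronal genes Nhlh2 was at 81.4 ± 4.4 CPM in D6RA and 0.0998 ± 0.063 CPM in D6DMSO, while Isl1 (3.72 ± 0.3 against 10.7 ± 1 CPM) and Phox2a (0.752 ± 0.049 against 1.93 ± 0.18 CPM) were lower. The call of Phox2a (adjusted p = 0.00207) was lost on thinning (0.591, within a range of 3.37e-05 to 0.591 over 15 alternatives). Neural progenitor genes were higher for 25 of 28 members and lower for 1 (list adjusted p = 1.54e-09 and 0.000859 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, was at 422 ± 6.1 against 0.418 ± 0.15 CPM, Pou3f3 at 121 ± 5.8 against 0.302 ± 0.037 CPM and Pax6 at 97.8 ± 3.1 against 6.98 ± 0.95 CPM. Scrt2, a zinc finger factor of neurons, had 2 counts in D6DMSO and 77 ± 4.1 CPM in D6RA, a ratio of 2680 (740 to 22100). Pantr1, a noncoding RNA, had 0 counts and 35.6 ± 1.8 CPM, at least 823-fold higher, and Msx3, of the dorsal neural tube, was at 196 ± 15 against 0.158 ± 0.15 CPM.

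Cardiac mesoderm genes were lower in D6RA for 14 of 16 members and higher for 0 (list adjusted p = 2.02e-06 and 0.00794 with an estimated correlation). Meox1 (0.358 ± 0.13 against 110 ± 22 CPM), Foxc2 (0.0435 ± 0.051 against 14.7 ± 3 CPM), Gata4 (0.0917 ± 0.0089 against 18.3 ± 4.4 CPM) and Gata6 (0.426 ± 0.15 against 43.4 ± 3.7 CPM) were lower. Tnni1 had 1 count in D6RA, 1600-fold lower (286 to 63200). Hcn4, a pacemaker channel of heart and neurons, was higher in D6RA (18.2 ± 1.1 against 6.59 ± 0.42 CPM). Endothelial and blood genes were lower for 12 of 15 members and higher for 0 (0.000158 and 0.00794), with Tal1 at 0.588 ± 0.15 against 16.1 ± 1 CPM and Etv2 at 1 count, 1220-fold lower (218 to 48100). Smooth muscle and mesenchyme genes were lower for 15 of 18 members and higher for 2 (list adjusted p = 0.000172, and adjusted p = 0.056 with an estimated correlation). Acta2, the smooth muscle actin, was at 1.57 ± 0.33 against 291 ± 27 CPM and Twist1 at 0.297 ± 0.045 against 32.7 ± 5.9 CPM. Vim, also an intermediate filament gene of neural progenitors, was higher (2210 ± 37 against 311 ± 18 CPM). All 11 epithelial genes were lower (list adjusted p = 2.15e-06, and adjusted p = 0.0532 with an estimated correlation). Krt18 was at 0.449 ± 0.11 against 214 ± 17 CPM and Krt19 at 3 counts, 1570-fold lower (537 to 7620). Cd36, a fatty acid transporter, had 2 counts in D6RA, also 1570-fold lower (435 to 13000).

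Pluripotency genes were lower in D6RA for 25 of 27 members (list adjusted p = 1.93e-09 and 0.00436 with an estimated correlation), among them Pou5f1 (log2 -9.22 ± 0.83, adjusted p = 3.83e-08) and Nanog (log2 -7.35 ± 0.31). L1td1 had 3 counts in D6RA, 333-fold lower (114 to 1620). Sox2 (log2 1.96 ± 0.16) and Esrrb (3.04 ± 0.65 against 0.652 ± 0.25 CPM) were the 2 members higher in D6RA. Proliferation genes were lower for 21 of 25 members and higher for 2 (list adjusted p = 1.52e-05, and adjusted p = 0.107 with an estimated correlation). Ccnb2 (30.9 ± 2.1 against 95.3 ± 6.8 CPM) and Aurkb (54.8 ± 2.7 against 125 ± 3.1 CPM) were lower, and Ccnd1 (122 ± 11 against 39.8 ± 3.4 CPM) and E2f1 (58.6 ± 3.6 against 24.6 ± 1.9 CPM) higher. Hypoxia and glycolysis genes were lower for 15 of 17 members and higher for 0 (list adjusted p = 8.71e-05, and adjusted p = 0.141 with an estimated correlation). Slc2a3 was at 14.7 ± 1.5 against 509 ± 32 CPM and Car9 at 0.14 ± 0.035 against 8.85 ± 1.1 CPM.

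The retinoic acid response list did not pass at day 6, with 6 members higher and 8 lower, or 6 and 9 adjusted over the list alone (list adjusted p = 0.41). Cyp26a1 was lower in D6RA (0.0923 ± 0.036 against 18.4 ± 0.57 CPM). Of the anterior Hox genes 11 were higher and 2 lower of 14 (list adjusted p = 0.0514, and adjusted p = 0.515 with an estimated correlation). That list passed with quantile normalization (0.0238), a proportional count (0.0228) and thinning (0.0055). Parietal endoderm, immediate early and streak genes were lower for 10 of 14, 12 of 17 and 12 of 17 members and higher for 2, 1 and 2 (list adjusted p = 0.000574, 0.00133 and 0.00199, and adjusted p = 0.107, 0.17 and 0.107 with an estimated correlation). T was at 0.115 ± 0.078 against 25.4 ± 0.25 CPM. Nuclear lamina genes were higher for 9 and lower for 4 of 19 (list adjusted p = 0.444), and H3K9 methylation genes higher for 14 and lower for 3 of 26 (0.0514, 0.0203 on thinning, and adjusted p = 0.138 with an estimated correlation). Skeletal muscle genes were higher for 2 and lower for 2 of 5 (list adjusted p = 0.839). Lmna was lower in D6RA (log2 -1.52 ± 0.22, adjusted p = 9.28e-06) and Lmnb1 higher (log2 0.36 ± 0.09, adjusted p = 0.0015). In total 9678 genes were called by limma with Benjamini-Hochberg adjustment, 4802 higher and 4876 lower in D6RA, of which 2187 and 2173 differed by at least 2-fold. With quantile normalization 4237 were higher and 5556 lower.

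The comparison of D6RA with D3RA asks what changed later under retinoic acid. Sez6 rose from 0.274 ± 0.24 to 52.5 ± 2.9 CPM (n = 3 per group; log2 7.2 ± 0.41, adjusted p = 3.08e-10). Grin2b, an NMDA receptor subunit, rose from 0.213 ± 0.37 to 22 ± 0.62 CPM, and Slc17a6, the vesicular glutamate transporter, from 0.569 ± 0.37 to 31.7 ± 4.5 CPM. Neuronal genes were higher for 32 of 39 members and lower for 2 (list adjusted p = 1.37e-06 and 0.0227 with an estimated correlation). Endothelial and blood genes were lower for 14 of 15 members and higher for 0, or 15 and 0 adjusted over the list alone (3.88e-06 and 0.00707), with Tek at 27.1 ± 4.9 and 0.731 ± 0.043 CPM.

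Rbfox3, which encodes the NeuN protein of mature neurons, rose from 1.25 ± 0.59 in D3RA to 19.2 ± 2.4 CPM in D6RA, and Tubb3 by 1.24 ± 0.09 on the log2 scale. Gap43 fell from 151 ± 19 to 59.9 ± 2.7 CPM. Nefl was at 148 ± 17 and 108 ± 8.9 CPM (adjusted p = 0.00735, lost on thinning all libraries to the smallest at 0.127, within a range of 0.000242 to 0.127 over 16 alternatives). Trim66 rose from 0.629 ± 0.55 to 79.8 ± 3.9 CPM. Proliferation genes were lower for 22 of 25 members and higher for 2 (list adjusted p = 1.3e-08, and adjusted p = 0.054 with an estimated correlation). Cdk1 fell from 230 ± 20 to 80.7 ± 0.53 CPM and Ccne1 from 42.5 ± 1.3 to 14.3 ± 0.58 CPM, while E2f1 and Ccnd1 rose by 1.28 ± 0.11 and 1.17 ± 0.12 on the log2 scale. Tal1 fell from 13.7 ± 1.2 to 0.588 ± 0.15 CPM.

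Pluripotency genes were lower in D6RA than in D3RA for 21 of 27 members and higher for 0 (list adjusted p = 3.88e-06 and 0.0227 with an estimated correlation), with Klf2 falling from 6.67 ± 0.73 to 0.487 ± 0.1 CPM. Pou5f1 was at 1.79 ± 2 and 0.115 ± 0.12 CPM (adjusted p = 0.000546, lost under voom weights at 0.114, within a range of 8.25e-05 to 0.114 over 16 alternatives), and Nanog had 3 and 5 counts, so no fold is given. Nanog was still called lower (adjusted p = 0.000209). Its call was lost with a count added in proportion to library size (0.974), under voom weights (0.234) and in the fit of the 6 libraries alone (0.0519). On thinning its log2 fold change was 0. The same 0.5 was added to counts of the shallower D3RA and deeper D6RA libraries, so other members near 0 in both may be among the 21. Parietal endoderm genes were lower for 9 of 14 members and higher for 1, and epithelial genes lower for 8 of 11 and higher for 0, or 9 and 0 adjusted over the list alone (list adjusted p = 0.00503 and 0.0083, and adjusted p = 0.231 and 0.269 with an estimated correlation). Pth1r fell from 109 ± 16 to 16.9 ± 0.88 CPM, Sox17, a factor of endoderm and endothelium, from 9.77 ± 1.7 to 0.949 ± 0.29 CPM, Krt18 from 5.45 ± 1.6 to 0.449 ± 0.11 CPM and Cldn6 from 1.28 ± 0.59 to 0.0572 ± 0.037 CPM. Lama1 rose from 99.8 ± 2.2 to 178 ± 11 CPM. T and Gata4 were lower (log2 -1.62 ± 0.46 and -2.49 ± 0.54, adjusted p = 0.00481 and 0.000668), calls that were lost on thinning (log2 -0.77 and -0.25, adjusted p = 0.187 and 0.725, within ranges of 0.00119 to 0.38 and 6.98e-08 to 0.725 over 16 alternatives). The T call was also lost with a count added in proportion to library size (log2 -0.42, adjusted p = 0.38) and in the fit of the 6 libraries alone (0.0946). Gata6 fell (log2 -1.94 ± 0.36), Lmnb1 rose (log2 0.48 ± 0.09), and Lmna and Sox2 were not called (adjusted p = 0.279 and 0.0649, the latter within a range of 0.00304 to 0.177 over 16 alternatives). Cyp26a1 fell by 6.93 on the log2 scale (± 0.25) and Csn3 by 6.3 (± 0.41). Pax6 was at 149 ± 8.2 and 97.8 ± 3.1 CPM (adjusted p = 0.0358), a call lost without any one of the 6 libraries (adjusted p = 0.0555 to 0.0917), without the trend (0.058) and on thinning (0.206, within a range of 6.33e-07 to 0.206 over 16 alternatives).

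In all, 10193 genes were called between D6RA and D3RA by limma with Benjamini-Hochberg adjustment, 5477 higher and 4716 lower in D6RA, of which 2525 and 1742 differed by at least 2-fold. With quantile normalization 4636 were higher and 5472 lower. The D6RA libraries hold 38.2 to 49.6 M counts against 3.55 to 9.82 M in D3RA, and mitochondrial counts that those lack, so day and these features of the libraries cannot be told apart here. Lars2, 1 of the 4 features named above, was among the lowest by log2 fold change (181000 ± 160000 against 2570 ± 3600 CPM).

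The comparison of D6DMSO with D3DMSO asks what changed later on the DMSO route. T fell from 874 ± 19 to 25.4 ± 0.25 CPM (n = 3 per group; log2 -5.1 ± 0.46, adjusted p = 1.24e-07), and Wnt3a from 42.7 ± 12 to 0.361 ± 0.12 CPM. Streak genes were lower for 16 of 17 members and higher for 1 (list adjusted p = 1.65e-08 and 0.0208 with an estimated correlation). Endothelial and blood genes were higher for 14 of 15 members and lower for 0 (1.51e-06 and 0.00466), Emcn having 0 counts in D3DMSO and 7.79 ± 1.4 CPM in D6DMSO, at least 48.2-fold higher. Sarcomere genes were higher for 11 of 14 members and lower for 0, or 12 and 0 adjusted over the list alone (list adjusted p = 1.46e-05, and adjusted p = 0.0522 with an estimated correlation).

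Ryr2, the calcium release channel of heart muscle, rose from 2.33 ± 0.49 in D3DMSO to 53.6 ± 9.3 CPM in D6DMSO. Tnnt2, the cardiac troponin T gene, rose from 3 counts to 4.99 ± 1.5 CPM, a ratio of 30.8 (10.5 to 150), and Ankrd1, a muscle ankyrin repeat gene, from 3 counts to 48.1 ± 8.7 CPM, a ratio of 298 (102 to 1450). Cardiac mesoderm genes were higher for 10 of 16 members and lower for 0, or 11 and 0 adjusted over the list alone (list adjusted p = 0.000902, and adjusted p = 0.0731 with an estimated correlation). Meox1 rose from 6.04 ± 1.4 to 110 ± 22 CPM, Myocd from 0.694 ± 0.079 to 12 ± 2.1 CPM and Gata6 from 14 ± 2.2 to 43.4 ± 3.7 CPM. Gata4 was not called (7.47 ± 1.2 and 18.3 ± 4.4 CPM, adjusted p = 0.0573), but it was in the fit of the 6 libraries alone (0.000479), under voom weights (0.000172) and on thinning (0.0433), within a range of 0.000172 to 0.171 over 16 alternatives. Fli1, a factor of blood and vessels, had 0 counts in D3DMSO and 21.5 ± 2.8 CPM in D6DMSO, at least 133-fold higher, and Gata2 rose from 0.195 ± 0.17 to 7.94 ± 0.43 CPM. Gsc fell from 16.3 ± 3.3 to 0.217 ± 0.09 CPM. Tbx3 was the streak member called higher (25.8 ± 3.5 against 12.4 ± 2.8 CPM, adjusted p = 0.0115), a call lost without D3DMSO replicate 1 (0.0571, within a range of 3.42e-05 to 0.132 over 16 alternatives).

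Posterior Hox genes were higher in D6DMSO than in D3DMSO for 9 of 10 members and lower for 0, and anterior Hox genes higher for 12 of 14 and lower for 1 (list adjusted p = 7.66e-05 and 0.000506, and adjusted p = 0.196 and 0.246 with an estimated correlation). Hoxb9 rose from 4.01 ± 2.8 to 95.4 ± 14 CPM, Hoxb6 from 0.549 ± 0.52 to 12.2 ± 1.8 CPM, Hoxb5 from 0.491 ± 0.47 to 13.8 ± 2.8 CPM and Hoxc4 from 0.978 ± 0.52 to 20.7 ± 0.79 CPM. Hoxb1 was at 36.4 ± 15 and 19.5 ± 4.1 CPM (adjusted p = 0.0233), a call lost without D3DMSO replicate 2, D3DMSO replicate 3, D6DMSO replicate 1 or D6DMSO replicate 2 (0.141, 0.0683, 0.0773 and 0.0851, within a range of 0.00187 to 0.141 over 16 alternatives). Nr2f1 had 1 count in D3DMSO and 53.1 ± 6.8 CPM in D6DMSO, a ratio of 985 (177 to 38900). Proliferation genes were lower for 19 of 25 members and higher for 3, or 19 and 4 adjusted over the list alone (list adjusted p = 0.000756, and adjusted p = 0.196 with an estimated correlation). Tyms and Ccne1 fell by 0.75 and 0.97 on the log2 scale (± 0.08 for both), and Ccnd1 and E2f1 rose by 1.15 ± 0.12 and 0.6 ± 0.11. The pluripotency list had 18 members lower and 3 higher of 27 (list adjusted p = 0.00201, and adjusted p = 0.109 with an estimated correlation). Pou5f1 fell by 3.48 on the log2 scale (± 0.83, adjusted p = 0.00199). Sox2 was at 67.4 ± 11 and 49.8 ± 16 CPM (adjusted p = 0.0218), a call lost without D3DMSO replicate 1, D3DMSO replicate 3, D6DMSO replicate 2 or D6DMSO replicate 3 (0.0972, 0.0544, 0.1 and 0.13, within a range of 0.000173 to 0.13 over 16 alternatives). Nanog, Cyp26a1 and Tubb3 fell (log2 -2.44 ± 0.31, -2.13 ± 0.25 and -2.59 ± 0.09) and Pax6 rose (log2 3.1 ± 0.24). Lmna rose by 1.03 ± 0.22 on the log2 scale and Lmnb1 was not called (adjusted p = 0.158).

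In all, 8302 genes were called between D6DMSO and D3DMSO by limma with Benjamini-Hochberg adjustment, 4172 higher and 4130 lower in D6DMSO, of which 1584 and 1127 differed by at least 2-fold. With quantile normalization 3813 were higher and 4722 lower. As with retinoic acid, the D6 libraries were deeper and held mitochondrial counts that the D3 libraries lack, and Lars2 was again among the lowest (93500 ± 77000 against 140 ± 48 CPM).

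Whether the difference between the treatments itself changed from day 3 to day 6 was tested as an interaction, the RA minus DMSO difference at day 6 less that at day 3. All 15 endothelial and blood genes were called in the same direction, with the level under retinoic acid lower against DMSO at day 6 than at day 3 (list adjusted p = 1.1e-11 and 0.00034 with an estimated correlation). Tek, an endothelial receptor, was at 27.1 ± 4.9 in D3RA and 0.695 ± 0.45 in D3DMSO but 0.731 ± 0.043 in D6RA and 14.4 ± 1.5 CPM in D6DMSO (n = 3 per group; log2 -9.58 ± 0.48, adjusted p = 1.09e-10). Emcn was at 19.3 ± 4.2, 0, 1.91 ± 0.55 and 7.79 ± 1.4 CPM in the same order (adjusted p = 6.54e-10). Fli1 was at 33 ± 4.7, 0, 1.05 ± 0.34 and 21.5 ± 2.8 CPM (adjusted p = 1.24e-12).

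**Figure D4:**
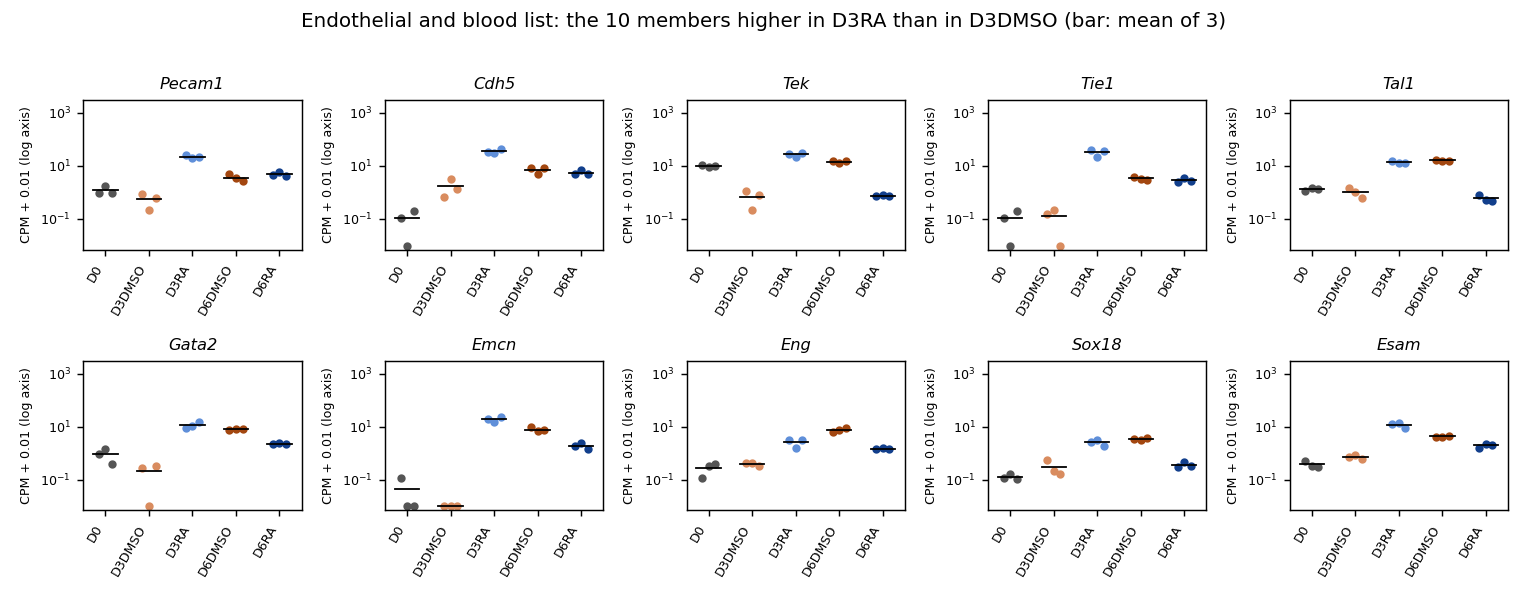
Levels in each library of the 10 endothelial and blood genes called higher in D3RA than in D3DMSO (y axis, CPM + 0.01 on a log axis; x axis, group; points, the 3 libraries; bar, their mean). Tek stood at 27.1 CPM in D3RA, 0.731 CPM in D6RA, 0.695 CPM in D3DMSO and 14.4 CPM in D6DMSO.

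Neuronal genes moved further towards retinoic acid by day 6 for 26 of 39 members and away from it for 3 (list adjusted p = 6.53e-08 and 0.0115 with an estimated correlation). Tubb3 gained 3.83 ± 0.13 on the log2 scale (adjusted p = 2.21e-12), Sez6 7.37 ± 0.58 and Rab3c, a synaptic vesicle GTPase, 7.3 ± 0.62. Gad1, which makes GABA, was at 3.31 ± 0.78 in D3RA and 6.93 ± 0.69 CPM in D3DMSO but 44.5 ± 2.6 in D6RA and 1.58 ± 0.085 CPM in D6DMSO. Slc17a6 was at 31.7 ± 4.5 CPM in D6RA, 0.569 ± 0.37 in D3RA, 0.0871 ± 0.12 in D6DMSO and 0 in D3DMSO. Gap43 went the other way (log2 -4.17 ± 0.21), as did Gad2 (log2 -1.88 ± 0.65, adjusted p = 0.0253). The Gad2 call was lost without D3DMSO replicate 1, D3DMSO replicate 3, D3RA replicate 2 or D6DMSO replicate 2 (0.0632, 0.0613, 0.0531 and 0.0603, within a range of 0.00183 to 0.0632 over 22 alternatives). Pax6 differed less at day 6 than at day 3 (log2 -3.71 ± 0.34, adjusted p = 1.91e-07), and Cyp26a1 went further down with retinoic acid (log2 -4.8 ± 0.36).

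Below, moved lower or higher means that the RA minus DMSO difference was lower or higher at day 6 than at day 3. Proliferation genes moved lower for 21 of 25 members and higher for 1 (list adjusted p = 2.75e-07, and adjusted p = 0.0582 with an estimated correlation). Cdk1 moved by -1.18 ± 0.1, Ccne2 by -0.89 ± 0.13 and E2f1 by 0.68 ± 0.16 on the log2 scale. Parietal endoderm genes moved lower for 12 of 14 members and higher for 2 (list adjusted p = 1.92e-05, and adjusted p = 0.0582 with an estimated correlation). Sox17 moved by -5.21 ± 0.53, Gata4 by -3.75 ± 0.77 and Gata6 by -3.57 ± 0.51, while Fst and Lama1 moved by 2.63 ± 0.28 and 2.16 ± 0.33. The Gata4 call (adjusted p = 0.000717) was lost on thinning (0.107, within a range of 9.52e-08 to 0.107 over 22 alternatives). Sox7 was at 8.88 ± 2.6 in D3RA, 0 in D3DMSO, 5.38 ± 0.48 in D6RA and 6.11 ± 0.87 CPM in D6DMSO. Hapln1, a link protein of the matrix, was at 73.1 ± 8.3 and 1.52 ± 0.89 CPM in D3RA and D3DMSO but 1.52 ± 0.38 and 103 ± 9.2 CPM in D6RA and D6DMSO (log2 -11.77 ± 0.44, adjusted p = 4.01e-12). Ankrd1 was highest in D6DMSO at 48.1 ± 8.7 CPM. Enpp2 went from 0.965 ± 0.41 against 143 ± 61 to 12.7 ± 0.8 against 7.97 ± 0.99 CPM. T moved by 3.48 ± 0.65 and Sox2 by 0.82 ± 0.23, while Pou5f1, Nanog and Lmna were not called (adjusted p = 0.8, 0.146 and 0.0512). Over 22 alternatives the adjusted p ran from 0.000644 to 0.621 for Nanog and from 0.0166 to 0.519 for Lmna. Lmnb1 moved by 0.33 ± 0.12 (adjusted p = 0.032, within a range of 0.000381 to 0.0852 over 22 alternatives), a call lost without D3DMSO replicate 3 (0.0558), D3RA replicate 1 (0.0755) or 2 (0.0852), D6DMSO replicate 1 (0.0732) or 2 (0.0552) and D6RA replicate 2 (0.078) or 3 (0.0517).

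The interaction was called for 7139 genes by limma with Benjamini-Hochberg adjustment, 3739 with a higher and 3400 with a lower difference at day 6, of which 1805 and 1562 changed by at least 2-fold. With quantile normalization 3321 were higher and 3882 lower, and with median-of-ratios scaling 3550 and 3555. With all libraries thinned to the smallest it was called for 4733.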

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

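The tests of mitochondrial genes against depth and against removal, the test of the endothelial list against mixing of cells, and the comparison of n-R5-8s1 with the ratios of the 4 features, were chosen after the result was seen, and the others were written before their values were computed.

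Every result in this paragraph stands out because the difference between the treatments was itself different at day 6 and day 3, by the interaction test. For lists the adjusted p was 6.53e-08 for neuronal differentiation, 2.75e-07 for proliferation, 1.92e-05 for parietal endoderm, 0.000116 for the retinoic acid response and for smooth muscle and mesenchyme, 0.00017 for cardiac mesoderm and 0.000174 for cardiac sarcomere. It was 0.000307 for anterior Hox, 0.000605 for posterior Hox, 0.000813 for the primitive streak, 0.0181 for skeletal muscle and 0.0405 for visceral and definitive endoderm, whose call was lost with quantile normalization (0.119) and, chosen after seeing the data, a proportional count (0.084) or thinning (0.0853). With an estimated correlation it was 0.0115 for neuronal differentiation and for the retinoic acid response and 0.0411 for cardiac mesoderm. Lists that lost the call were proliferation, parietal endoderm, smooth muscle and sarcomere (adjusted p = 0.0582 with an estimated correlation for each), streak and visceral endoderm (adjusted p = 0.0901 with an estimated correlation for both), skeletal muscle (adjusted p = 0.122 with an estimated correlation) and the Hox lists (adjusted p = 0.267 with an estimated correlation for both). The next counts are members whose RA minus DMSO difference was lower, then higher, at day 6 than at day 3. They were 12 and 2 of 16 for the retinoic acid response and 12 and 3 of 18 for smooth muscle. Cardiac mesoderm had 10 and 2 of 16 (11 and 2 adjusted over the list alone) and sarcomere 10 and 2 of 14. Anterior Hox had 12 and 0 of 14 and posterior Hox 9 and 0 of 10. The streak had 2 and 11 of 17 and skeletal muscle 4 and 0 of 5. Such a difference can also change through the DMSO groups. From D3RA to D6RA, 1 anterior Hox gene was called higher and 3 lower (0 and 3 adjusted over the list alone). In the streak list 3 were higher and 12 lower, and that list did not pass (list adjusted p = 0.0912, and adjusted p = 0.348 with an estimated correlation). T, a member, was near 0 in both groups (0.278 CPM in D3RA and 0.115 CPM in D6RA). The same 0.5 was added to counts of shallower and deeper libraries, so other streak members near 0 in both may be among the 12. From D3DMSO to D6DMSO, 12 anterior Hox genes were higher and 1 lower, and 1 streak gene was higher and 16 lower. Panel genes with a called interaction were Sox2 (log2 0.82), Cyp26a1 (-4.8), Pax6 (-3.71), Tubb3 (3.83), T (3.48), Gata4 (-3.75), Gata6 (-3.57) and Lmnb1 (0.33). For Pax6, Tubb3, Gata4 and Lmnb1 the adjusted p from limma with Benjamini-Hochberg adjustment are in the report.

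The endothelial and blood list had the lowest interaction p (1.1e-11). Unequal counts added before the log2 would end the call when a count is added in proportion to library size, and the adjusted p was then 5.03e-12. A single library would end it when left out, and the highest adjusted p without each of the 12 libraries was 9.61e-11. If cells of another group had been mixed into the D3RA libraries, each of the 10 members called higher in D3RA than in D3DMSO would stand higher in another group, but 7 of them (Pecam1, Cdh5, Tek, Tie1, Gata2, Emcn and Esam) had their highest mean in D3RA. The other members, Tal1, Eng and Sox18, had their highest mean in D6DMSO. These values go against the added count and a single library as explanations, and against mixing as the only source for those 7 members. They cannot tell whether mixing added to part of the levels. No biological explanation was tested.

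All 11 mitochondrial genes were at 0 in D0 and D3. Lower depth goes against the values, since the smallest library would hold 2.52 M mitochondrial counts at the lowest D6 share. Removal or absence from counting before deposit stays open, since the 0 counts (at most 4.77e-06% of 62.8 M) are the pattern itself and decide nothing, while 94 of 97 nuclear genes of the respiratory chain were counted in all 9 libraries. As a biological explanation, lower respiratory chain expression in the earlier cells would show as a rise of these nuclear genes by day 6, but their median log2 change was -0.65 with retinoic acid and -0.55 with DMSO. These values cover the respiratory chain only. They cannot speak for the ribosomal RNA genes mt-Rnr2 and mt-Rnr1, which took 31.6 to 42.5% and 6.55 to 11.1% of all counts in the D6 libraries. The comparisons between days cannot separate this difference from time.

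Lars2, Gm15564, ENSMUSG00000045999 and ENSMUSG00000093077 took 1.97 to 45.7% of the non-mitochondrial counts among the 3 D3RA libraries. Ribosomal RNA reads counted on these features would raise the 5.8S ribosomal RNA gene n-R5-8s1 in the same libraries. In replicates 2 and 3 it stood 15 times higher than in replicate 1 in D3DMSO and 2.45 times higher in D3RA. Both values met the prediction written beforehand, which was 2 times or more in both D3 groups. The 4 features stood 6.48 to 16 times higher in D3DMSO but 16.8 to 62.6 times higher in D3RA. By that comparison, chosen after the result was seen, n-R5-8s1 rose less than the 4 features in D3RA, so this explanation stays open. A shift in the scale of other genes stays open too, since the deposited scale had already brought the median log2 difference of the other genes between D3RA replicates 3 and 1 to -0.027 (scaled size over non-mitochondrial counts of 0.6168 and 1.1177). No biological explanation was tested.

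Of the 10 possible splits of each comparison's 6 libraries, 1 gave as many called genes as the real one, which is the real split itself. The highest count of any other split was 0, or 1 for D3RA with D3DMSO, and 10 splits are too few for a share under 0.05. For the interaction, 2 of 100 joint splits gave as many genes, the real one included, and the other (10362 genes) swaps the treatment of all D3 libraries. Splits that mix the treatments also break the treatment difference within a day. This share therefore cannot tell whether that difference changed between the days.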

How the results depend on the processing

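Every count of called genes stayed within 1.5 times its value under each alternative, except the interaction, called for 4733 genes on thinning (chosen after seeing the data), where fewer counts are tested. Counts over all alternatives ran from 5878 to 8408 for D3DMSO with D0, 8202 to 10296 for D3RA with D0, 6953 to 9287 for D3RA with D3DMSO, 7842 to 11413 for D6RA with D6DMSO, 7986 to 10471 for D6RA with D3RA, 5956 to 9036 for D6DMSO with D3DMSO and 4733 to 7539 for the interaction. Without each library in turn they ran from 7425 to 8121, 9606 to 10004, 8671 to 8948, 8890 to 9066, 9378 to 10042, 7233 to 8078 and 6372 to 7261. With an estimated correlation, 1 list of 8 kept its call in D3DMSO with D0, 5 of 12 in D3RA with D0, 5 of 13 in D3RA with D3DMSO, 6 of 13 in D6RA with D6DMSO, 3 of 10 in D6RA with D3RA, 2 of 13 in D6DMSO with D3DMSO and 4 of 13 in the interaction. The same-direction overlap of the D0 comparisons was 1322 genes at a log2 fold change of at least 1, where fewer genes enter, and 4650 to 4796 without each D0 library. Directions turned for Lmnb1 in D3RA with D3DMSO (not called; -0.06 with quantile normalization, -0.1 without D3RA replicate 3 to 0.11 without D3RA replicate 2, 0 with voom), for Pou5f1 in the interaction (not called; 0.49 with quantile normalization, 0.54 without D3RA replicate 3, -1.35 without D3RA replicate 1 to 0.75 without D6RA replicate 3, 0.21 with voom, 1.05 with a proportional count, 1.51 thinned), for Nanog in D3DMSO with D0 (not called; -0.48 without D3DMSO replicate 1 to 0.06 without D3DMSO replicate 2) and, thinned, for Pax6 in D3DMSO with D0 (0.65) and Nanog in D6RA with D3RA (0). The cause was not tested. Voom, proportional counts and thinning, on counts recovered from the log2 values, were chosen after seeing the data. Using no filter changed nothing, and DESeq2, edgeR with other size factors and a smaller pseudocount, tied in the plan to a table of counts or of CPM, were not run, since the deposited table holds log2 values. Depth limits genes with few counts in D0 and D3. Over all genes the replicate numbers did not pair the libraries (D3DMSO and D3RA correlated at 0.21, 0.06 and 0.08 by number), though every library correlated best with its own number in 4 of 10 pairs of groups. Over genes of at least 10 CPM, every correlation was over 0.1 for D3DMSO with D3RA (0.37, 0.14 and 0.2) and for D0 with D3DMSO (0.24, 0.13 and 0.4) but for no other pair of groups, so a shared batch at D0 and D3 is left open. With a replicate block the counts were 8408, 10296, 9287, 9808, 10263, 8418 and 7323 in the order above, and in D6RA with D6DMSO the anterior Hox and H3K9 methylation lists passed (adjusted p = 0.0374 and 0.0328). Without the block and with an estimated correlation these 2 lists did not pass (adjusted p = 0.515 and 0.138). Of the named genes, the block ended the call of Smarcd3 in D3RA with D3DMSO (0.056) and gave one to Sox2 in D6RA with D3RA (0.0377).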

Other observations

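The lists of this part were fixed in advance, and the count of genes shared between the day comparisons was chosen after the result was seen.

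Within the neural progenitor list, genes split between D3RA and D6RA, 16 higher and 5 lower of 28 (list adjusted p = 0.0412, and adjusted p = 0.151 with an estimated correlation). Neurog2, a proneural factor, rose from 3.47 ± 0.6 to 17.9 ± 0.49 CPM (n = 3 per group; log2 2.33 ± 0.51, adjusted p = 0.000718 from limma with Benjamini-Hochberg adjustment). Dbx1, a factor of intermediate neural tube progenitors, fell from 37.6 ± 7.1 to 1.19 ± 0.16 CPM. Neurog1 was at 25.4 ± 4.9 and 7.81 ± 0.71 CPM (adjusted p = 0.0192), a call lost without D3RA replicate 3, D6RA replicate 2 or D6RA replicate 3 (0.0636, 0.0577 and 0.0543, within a range of 1.74e-08 to 0.0636 over 16 alternatives). The list lost its call without D3RA replicate 1 (0.0516) or D3RA replicate 2 (0.0688). Retinoic acid response genes were lower in D6RA for 10 of 16 members and higher for 3, or 10 and 4 adjusted over the list alone (list adjusted p = 0.0127, and adjusted p = 0.054 with an estimated correlation). Smooth muscle genes were lower for 11 of 18 members and higher for 4, and hypoxia genes lower for 9 of 17 and higher for 3 (list adjusted p = 0.0127 and 0.0136, and adjusted p = 0.231 and 0.371 with an estimated correlation).

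From D3DMSO to D6DMSO, smooth muscle and mesenchyme genes were higher for 12 of 18 members and lower for 3, or 12 and 4 adjusted over the list alone, and immediate early genes higher for 10 of 17 and lower for 0 (list adjusted p = 0.00443 and 0.00471, and adjusted p = 0.178 and 0.246 with an estimated correlation). Hypoxia genes were lower for 11 of 17 members and higher for 3 (list adjusted p = 0.00352, and adjusted p = 0.246 with an estimated correlation), and skeletal muscle genes higher for 4 of 5 and lower for 0 (list adjusted p = 0.0209, and adjusted p = 0.187 with an estimated correlation). Parietal endoderm genes were higher for 9 of 14 members and lower for 2, or 10 and 2 adjusted over the list alone (list adjusted p = 0.0179, and adjusted p = 0.246 with an estimated correlation). Pax3, a factor of both somites and the dorsal neural tube that stands on the skeletal muscle list, was at 102 ± 1.3 CPM in D3RA and 0.19 ± 0.21 in D3DMSO, and at 218 ± 3.8 in D6RA and 10.9 ± 1.2 CPM in D6DMSO (interaction log2 -4.49 ± 0.49, adjusted p = 1.2e-06 from limma with Benjamini-Hochberg adjustment). In the interaction, the RA minus DMSO difference of visceral and definitive endoderm genes was lower at day 6 for 6 of 8 members and higher for 1 (list adjusted p = 0.0405, and adjusted p = 0.0901 with an estimated correlation). This list lost its call with quantile normalization (0.119), a proportional count (0.084) and thinning (0.0853). Cxcr4, a chemokine receptor also found on neurons, moved higher (122 ± 2.2 in D6RA and 6.57 ± 1.1 in D6DMSO against 35.4 ± 3.3 in D3RA and 24.5 ± 2.1 CPM in D3DMSO). Neural crest and glia genes passed in no comparison, with 5 higher and 5 lower of 10 in D3RA against D3DMSO (list adjusted p = 0.51) and 4 and 4 in D6RA against D6DMSO (0.73). From day 3 to day 6, 596 genes were at least 2-fold higher in both treatments and 370 lower in both, against 272 and 133 for independent lists, and 541 went in opposite directions, against 381. Both comparisons also share the greater depth and the mitochondrial counts of the D6 libraries.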
